A study of Mus musculus with 2 samples.

How the data were processed

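MicroRNA-seq of total RNA from mouse stomach at embryonic day 15.5, size selected below 30 nt, was available for 2 libraries, biological replicates 1 and 2, each from a separate pool of embryos per the labels. The deposited values were whole-number read counts per miRNA gene, 1 table per library, for the mm10 assembly and the GENCODE M4 annotation per the deposited description files. The aligner, trimming and counting tool are not given in the sources used here. The tables have no header. The meaning of the columns was read from the values: in every gene row the first count equals the sum of the other 2, and nearly all counts of known miRNA genes are in the second, which was taken as the sense strand and used throughout. The third count was taken as the opposite strand.

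Each table also has lines that name no gene, which were kept out of library totals and tests. Of 11558785 reads in replicate 1 and 12633753 in replicate 2, reads matching several places made up 25.5% and 27.0%, unmapped reads 18.0% and 16.2%, and reads outside annotated miRNA genes 2.92% and 2.26%. Multi-mapping reads are a line of their own, so genes with near-identical copies elsewhere may lose reads. Sense-strand gene counts made up 51.8% and 52.8% and opposite-strand counts 1.81% and 1.69%.

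Symbols and coordinates come from GENCODE M21 on the same assembly, matched by gene identifier without its version; 1894 of 1973 identifiers matched, and the 79 others had 2 summed sense counts in all. Counts were divided by the library total of sense miRNA gene counts and given as CPM, with means and SD over 2 pools. Ratios are log2 of replicate 2 over replicate 1 with 1 CPM added. Shares of single libraries have 95% Wilson intervals and ratios 95% exact Clopper-Pearson intervals. These and the zero-count limit of 3 counts cover counting error only, since reads are not independent molecules.

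With 1 group there is no test between conditions. Each gene with at least 10 summed counts was compared between the libraries by a two-sided exact conditional binomial test with Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05 and a log2 ratio of at least 1 in size. The biological coefficient of variation is the root of edgeR's common dispersion with an intercept-only design; the same dispersion was used in edgeR's exact test. That dispersion counts the difference between the pools as spread. Medians of 19 gene lists were placed among 10000 random lists, for differences between libraries matched on mean expression by drawing each gene from its 50 nearest. Tests, lists, 32 clusters and the rule for named genes were fixed before the data were examined. Named were the 20 genes of highest mean CPM, up to 4 top members of each list, members of clusters whose highest gene had 10 counts in both libraries, and up to 5 called genes per direction of largest ratio with at least 100 summed counts. Mir495, Mir133a-1, Mir133a-2 and Mir1a-1 fall outside that rule and were chosen after their values were seen, as were the genes overlapped on the other strand; the acinar pancreas genes were chosen for their test.

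The steps were tested on simulated counts with the real gene means and library totals, with 200 genes changed outside the 20 most abundant. The exact test between the libraries was simulated with counting noise only, so its rates do not cover spread between pools. It called 75% of genes changed by 1.5 on the log2 scale and 91% of those changed by 3. Tested were 458 genes, and 0.741% of unchanged genes were called. With no change and counting noise only, 0 of 468 genes were called and the chi-square per degree of freedom was 1.07. A simulated coefficient of variation of 0.2 was estimated at 0.198 over 470 genes. Alternatives covered scaling, count minimum, fold limit, pseudocount, strand column, copies and leaving out each replicate. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.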

Results

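Small RNA shorter than 30 nt was sequenced from whole stomach of mouse embryos at embryonic day 15.5, when the gut wall already holds muscle, mesenchyme and epithelium. Replicate 1 was a pool of 78 embryos and replicate 2 a pool of 62 embryos, both of mixed sex and of the B6NCrl strain. They form 1 group with no second condition, so the comparisons are between miRNA genes within the tissue and between the 2 pools. The sense-strand counts of miRNA genes summed to 5988677 in replicate 1 and 6675498 in replicate 2. A count of 0 allowed up to 0.501 CPM (the count scaled to a common library total) in replicate 1 and 0.449 CPM in replicate 2. Intervals and these limits cover counting error only.

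A few genes held most of the sense-strand counts assigned to miRNA genes. Reads matching several places are not among these counts, so genes with near-identical copies may be ranked too low or be missing below. The shares, the order and the numbers of genes therefore describe the counted reads, not the whole stomach miRNA pool. Mir143, a miRNA of smooth muscle on chromosome 18 (61649196 to 61649258, minus strand), alone held 17.8% ± 0.413 of the counts (SD, n = 2). Next came Mir99a with 5.85% ± 0.236, Mirlet7g with 5.38% ± 0.275, Mir335 with 5.17% ± 0.565 and Mirlet7i with 5.02% ± 0.0864. Mir10a, which lies in a Hox cluster, held 3.82% ± 0.60, and Mir126a, the endothelial miRNA, 2.56% ± 0.0830. In each library 9 genes held 50% of the counts, and 62 genes in replicate 1 and 57 in replicate 2 held 90%. Of the 1973 miRNA genes listed, 369 had at least 10 counts in both libraries and 1247 had none in either. The other genes among the 20 most abundant were Mir26b, Mir130a, Mir17, Mir23b, Mir322, Mir429, Mir375, Mir23a, Mir200c, Mir99b, Mir30e, Mirlet7d and Mir21a, at between 12668 CPM for Mir21a and 32315 CPM for Mir26b.

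Muscle and mesenchyme genes differed widely in level. The smooth muscle list held 18.3% ± 0.346 of the counts (SD, n = 2), nearly all of it Mir143 (0.509% with that gene left out of list and total). Mir145a, transcribed with Mir143, stood at 2487 ± 613 CPM and Mir28a at 1694 ± 62.2 CPM. The list of heart and skeletal muscle genes held 0.0231% ± 0.00441, led by Mir206 at 149 ± 60.5 CPM and Mir208b at 67.1 ± 10.2 CPM. Mir133a-1 and Mir133a-2 had no counts in either library. But these and Mir1a-1 have near-identical copies whose shared reads may have been left out, so their levels, and that of the list, are uncertain. The mesenchyme list held 1.53% ± 0.338, with Mir214 at 7072 ± 173 CPM, Mir10b at 5252 ± 2760 CPM, Mir140, a cartilage miRNA, at 1560 ± 227 CPM and Mir199b at 1023 ± 202 CPM.

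Epithelial genes were abundant in both pools. The miR-200 family, which marks epithelial identity, held 4.35% of counts in replicate 1 (95% Wilson interval 4.33 to 4.37) and 4.32% in replicate 2 (4.30 to 4.33). Its members were Mir429 at 18732 ± 337 CPM, Mir200c at 14202 ± 326 CPM, Mir200b at 7293 ± 759 CPM, Mir141 at 1916 ± 37.1 CPM and Mir200a at 1201 ± 88.5 CPM. Markers of stratified epithelium, such as lines the mouse forestomach, were present beside those of glandular epithelium: Mir203 stood at 7638 ± 2271 CPM and Mir205 at 6866 ± 1544 CPM. Mir182 (3510 ± 260 CPM), Mir183 (2656 ± 13.3 CPM) and Mir96, a cluster known from sensory epithelium, belong to the same list. In the glandular list Mir375, also a miRNA of endocrine cells, led with 18048 ± 7315 CPM, followed by Mir215 at 2024 ± 474 CPM, Mir192 at 1507 ± 5.24 CPM and Mir148a at 1016 ± 25.4 CPM. The stratified and sensory list held 2.22% ± 0.422 of the counts and the glandular list 2.36% ± 0.777.

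**Figure D1:**
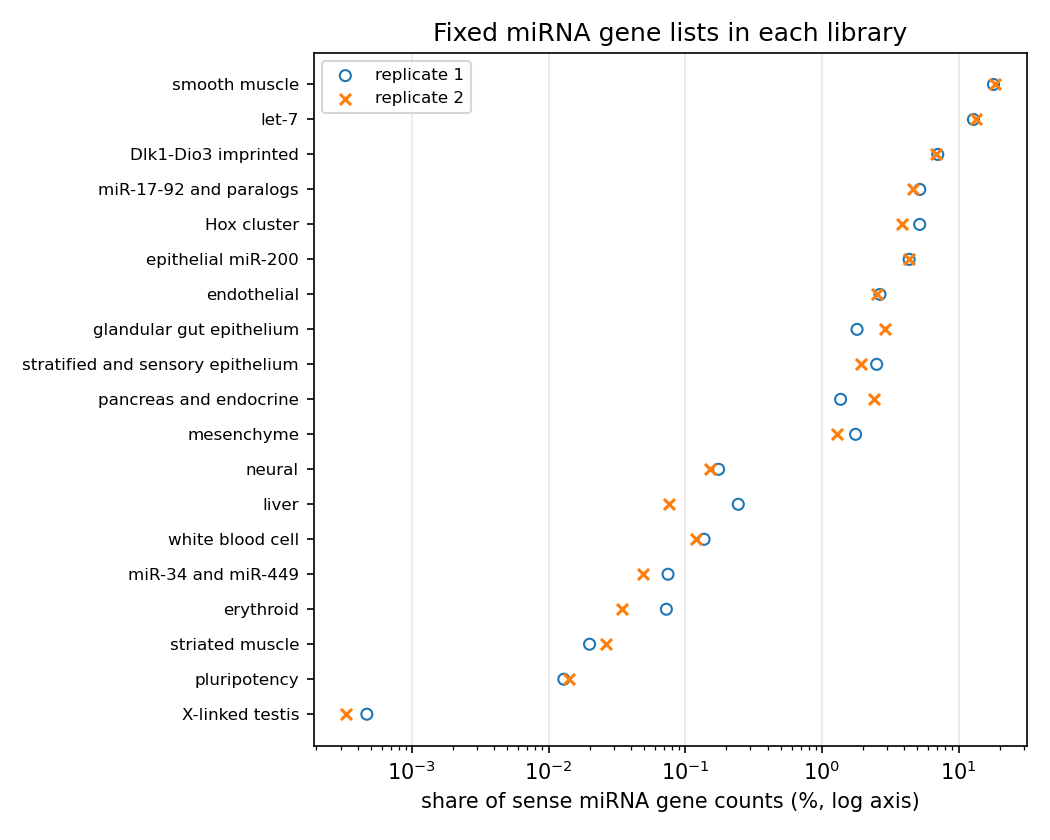
Share of sense-strand miRNA gene counts (percent, log axis) held by each of the 19 gene lists, with 1 point per library and no error bar. The smooth muscle list is highest, with 18.5% in replicate 2, and the erythroid and liver lists are among those with the points farthest apart.

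Among the lists, let-7 came next after smooth muscle. The let-7 share leaves out Mirlet7e and Mirlet7f-1, which are not listed genes, and reads shared between copies may be missing. It may therefore be too low. The let-7 family, which rises through development, held 13.2% ± 0.474 of counts (SD, n = 2) over 10 listed genes, and the miR-17-92 cluster with its paralogs, linked to proliferation, held 4.92% ± 0.406 over 15. In the latter, Mir17 stood at 21613 ± 1665 CPM, Mir93 at 8210 ± 344 CPM and Mir20a at 7788 ± 1012 CPM. The Hox-embedded list held 4.51% ± 0.966. The stem cell clusters held 0.0135% ± 0.000755, with Mir302a at 49.8 ± 1.14 CPM.

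Markers of blood, vessels, nerves and neighbouring organs were measured in the same libraries. The endothelial list held 2.60% ± 0.0926 of the counts (SD, n = 2) and the neural list 0.164% ± 0.0159, with Mir137 at 1240 ± 130 CPM. With near-identical copies counted once, the 15 neural genes came to 8. Reads shared between copies may be missing, so the neural share may be too low and the lead of Mir137 is uncertain. The pancreas and endocrine list held 1.89% ± 0.735, most of it Mir375, with Mir7b at 601 ± 28.5 CPM. The white blood cell list held 0.129% ± 0.0117, led by Mir223, a myeloid miRNA, at 1180 ± 95.6 CPM; with both strands counted the list held 0.262%, since Mir142b had opposite-strand counts. Mir122, the main miRNA of hepatocytes and sole member of the liver list, held 0.160% ± 0.119, and the erythroid list 0.0536% ± 0.0271. The miR-34 and miR-449 list held 0.0621% ± 0.0181. The X-linked testis list, taken as a low reference, held 0.000399% ± 9.76e-05. Against 10000 random lists of the same size from all miRNA genes, 18 of 19 lists had a median at or above the 95th percentile; the X-linked testis list lay at the 42.1 percentile. Against random lists from genes with at least 10 summed counts, 6 lists did so: smooth muscle, miR-200, stratified and sensory, glandular, let-7 and Dlk1-Dio3. The first comparison says little, since 1247 of the 1973 miRNA genes had no counts in either library. Striated muscle lay at the 98.8 percentile in the first and the 14.1 percentile in the second.

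The imprinted Dlk1-Dio3 region on chromosome 12, whose miRNAs are expressed from the maternal allele, held abundant miRNA genes in separate blocks. The 47 genes of its list lay between 109563692 and 109747960 and held 6.93% ± 0.168 of the counts (SD, n = 2), with 44 of them at 10 counts or more in both libraries and 15 at 1000 CPM or more. Among listed genes counted on the sense strand, Mir411 was the highest at 11624 ± 707 CPM, followed by Mir127 at 9049 ± 11.8 CPM, Mir487b at 7490 ± 5.02 CPM and Mir369 at 6086 ± 788 CPM; opposite-strand counts in the region, such as 39087 and 50625 at Gm24321, are in neither this order nor the share. Of the 45 members tested between the pools, 1 passed the test: Mir495 fell by 1.45 on the log2 scale in replicate 2, from 1433 to 582 counts.

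**Figure D2:**
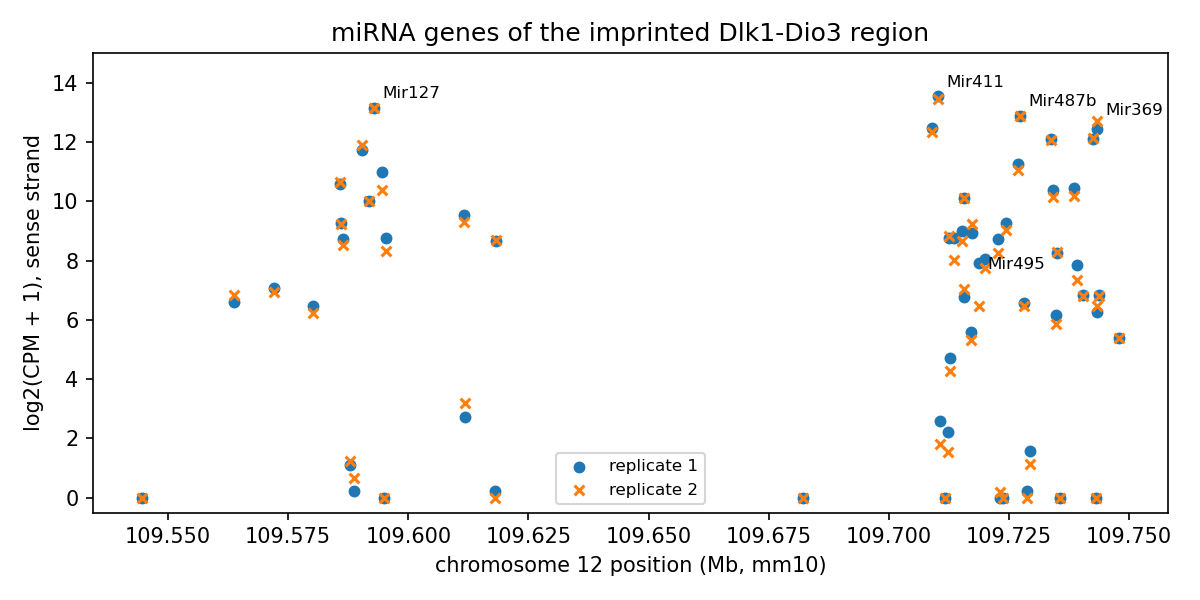
log2(CPM + 1) of sense-strand counts of each miRNA gene (vertical axis) against its position on chromosome 12 in Mb, mm10 (horizontal axis), with 1 point per library. Mir411, with a mean of 11624 CPM, is the highest, and Mir495 is the labelled gene whose points lie apart.

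miRNA genes of the same genomic cluster, which can share a primary transcript, were counted at very different levels. Over 29 clusters the highest member exceeded the lowest by a median of 4.23 on the log2(CPM + 1) scale, and the range was 0.42 to 10.86. In the miR-17-92 cluster Mir17 exceeded Mir19b-1 by 10.86 ± 0.29 (SD, n = 2), and Mir19a, at 45.7 ± 8.98 CPM, was also low. Mir143 exceeded Mir145a by 6.19 ± 0.39, Mir99a exceeded Mirlet7c-1 by 8.51 ± 0.08 and Mir214 exceeded Mir199a-2 by 5.88 ± 0.05. Other clusters were nearly even: Mir181c exceeded Mir181d by 0.42 ± 0.04 and Mir15a exceeded Mir16-1 by 0.56 ± 0.29. The SD of a span between the pools had a median of 0.17. Reads that matched several places were left out of the gene counts. Levels of genes with near-identical copies, such as Mirlet7c-1, Mir199a-2, Mir19b-1 and Mir16-1, are therefore uncertain, as are spans that rest on them. Mirlet7e, Mirlet7f-1, Mir24-1 and Mir450a-1 were not measured in their clusters. Mir29b-1 and Mir29b-2 stood near the floor. With pseudocount 5 the span from Mir29a to Mir29b-1 went from 5.98 to 4.15 and that from Mir29c to Mir29b-2 from 5.06 to 3.26.

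**Figure D3:**
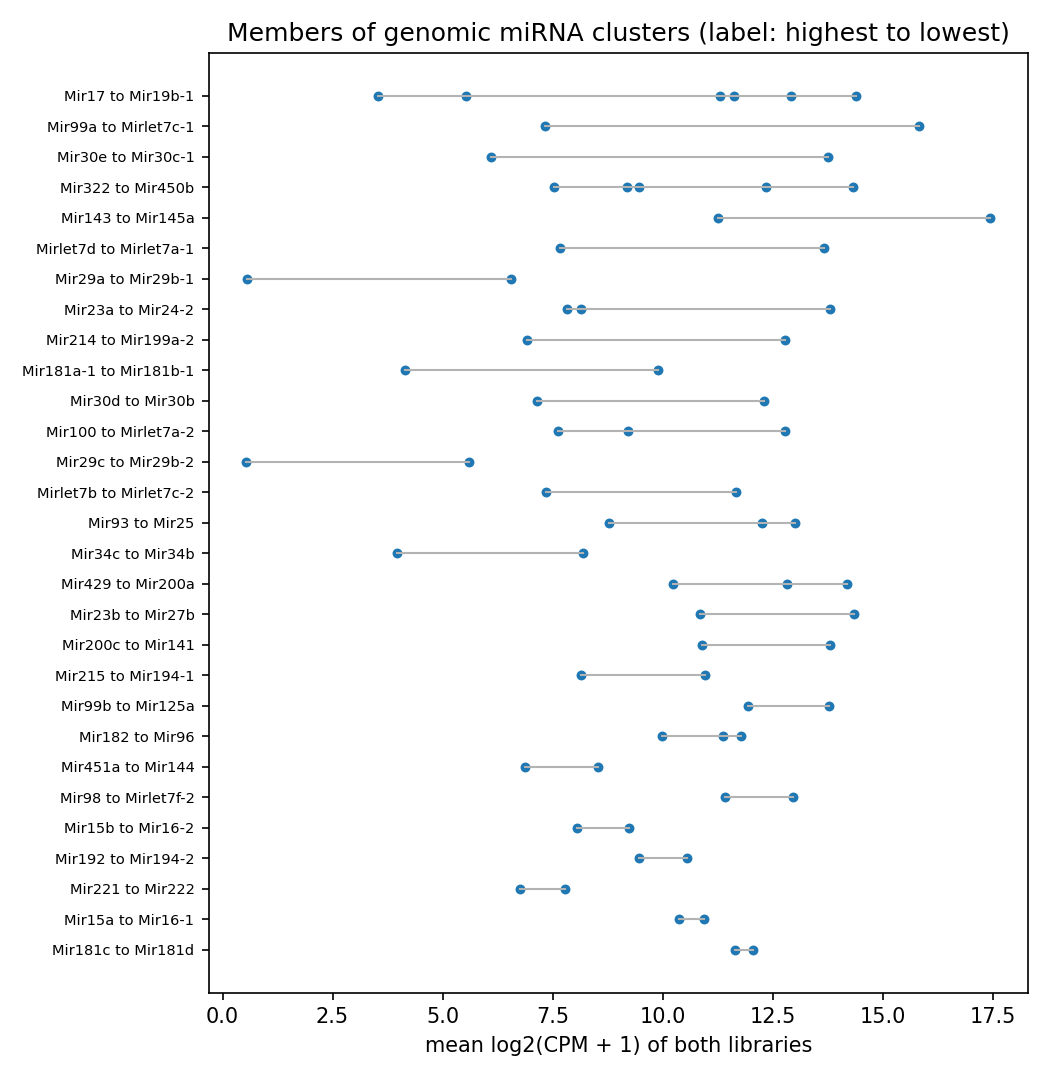
Mean log2(CPM + 1) over both libraries (horizontal axis) of the members of 29 genomic clusters, with 1 point per gene and a line from the lowest to the highest; row labels name these members. Spans run from 0.42 for Mir181c and Mir181d to 10.86 for Mir17 and Mir19b-1.

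The pools gave similar profiles. Across 466 genes with at least 10 summed counts, Pearson's r of log2(CPM + 1) was 0.994 and Spearman's rho 0.982; genes are not independent replicates, so no p is given. Of these genes, 94.2% lay within 2-fold. The chi-square statistic over the same genes was 204 per degree of freedom, a description only, since it sets separate pools against counting error alone. The biological coefficient of variation between the pools, from edgeR, was 20.1%, or 0.201 as a fraction. The root of the median gene-wise dispersion from DESeq2, also a coefficient of variation, was 0.0644. It is a median over genes, while edgeR's is 1 value fitted over all genes.

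Lower in replicate 2 than in replicate 1 by the test were Mir122 of the liver list, the 3 erythroid genes, 3 of the 5 tested Hox-embedded genes and 2 of the 11 tested neural genes. These calls depend in part on the scaling: with DESeq2 size factors 0 of 3 erythroid and 2 of 5 Hox-embedded genes stayed past the 2-fold limit, and with TMM 1 and 2. By the exact binomial test with a 2-fold limit, 24 genes were lower and 3 higher in replicate 2, 27 in all. Mir196a-2 fell by 2.32 on the log2 scale (95% exact interval -2.66 to -2.10; 600 against 129 counts), Mir129-1, a neural miRNA, by 1.91 (-2.56 to -1.58), Mir122 by 1.69 (-1.74 to -1.65; 14641 against 5051 counts), Mir196b by 1.66 (-1.73 to -1.61) and Mir129-2 by 1.60 (-2.18 to -1.27). Mir181a-2 was the 1 gene with at least 100 summed counts that passed the test in the other direction. It was higher in replicate 2 by 1.15 (0.95 to 1.39, with 249 against 624 counts). Mir181a-1, a numbered copy of the same miRNA, stood at 0.06 (5550 against 6467 counts). Mir375 was higher by 0.85 (0.84 to 0.86; 77112 against 155010 counts) and Mir206 by 0.85 (0.72 to 0.99), both under the fold limit. The test compares these libraries, not conditions. Mir196a-2, Mir129-1, Mir129-2 and Mir181a-2 carry copy numbers, and reads shared between copies may be missing from their counts. The 2 neural calls, Mir129-1 and Mir129-2, are numbered copies of the same miRNA. edgeR's exact test, with a dispersion estimated from the same 2 libraries, passed 4 genes, Mir196a-2, Mir129-1, Mir122 and Mir196b; it marks genes that differed more than the typical gene and holds no replicate of either pool. DESeq2 size factors gave 6 higher and 16 lower genes.

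**Figure D4:**
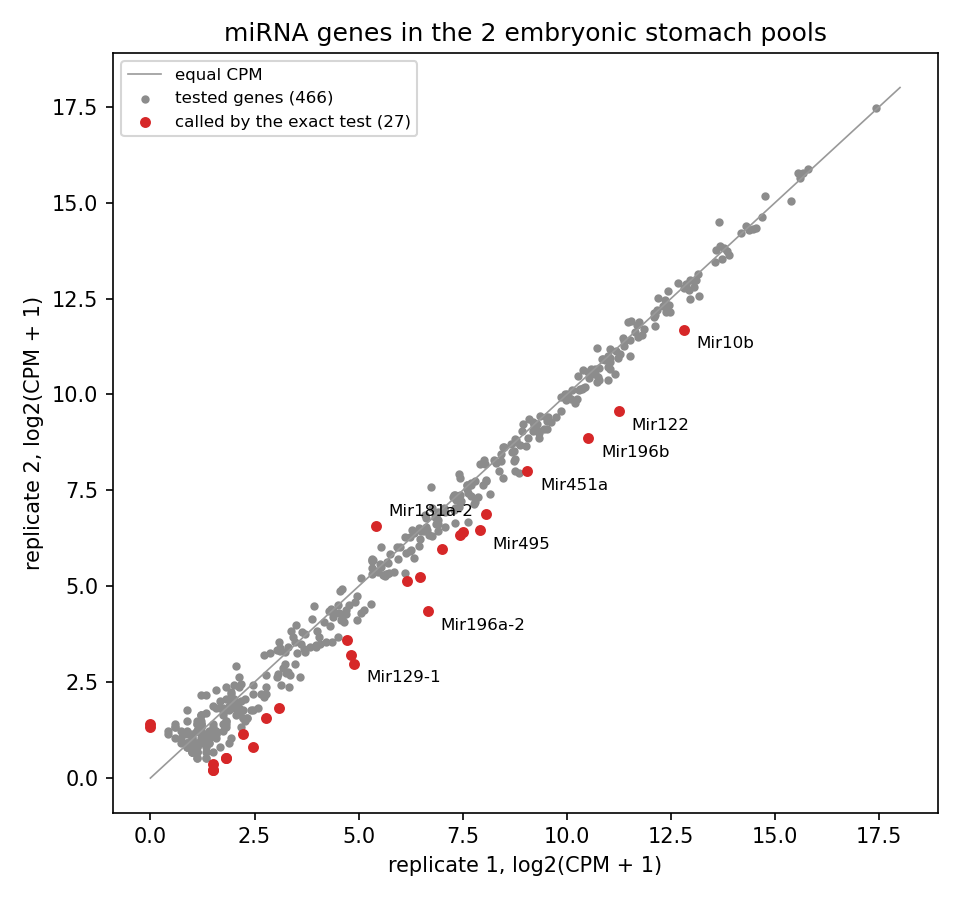
log2(CPM + 1) in replicate 2 (vertical axis) against replicate 1 (horizontal axis) for 466 tested miRNA genes, with a line at equal CPM and the 27 genes called by the exact test in red. Of those, 24 lie below the line and 3 above.

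Some lists had a median ratio between the pools unlike that of random lists. The 5 tested Hox-embedded genes were all lower in replicate 2, with a median log2 ratio of -1.13; Mir10b (-1.13), Mir196b and Mir196a-2 passed the test, and Mir10a (-0.32) and Mir615 (-0.41) did not. The 3 erythroid genes Mir144 (-1.10), Mir451a (-1.06) and Mir486 (-1.13) all fell, with a median of -1.10. Both medians lay below the central 95% of 10000 expression-matched random lists, as did those of the liver list (Mir122 alone) and of the miR-34 and miR-449 list (-0.72), in which Mir449a fell by 1.08. The glandular list (0.14) and the let-7 list (0.08) lay above it, with no member past the test. Their members went both ways, 4 higher and 2 lower in the glandular list and 8 higher and 2 lower in let-7. Without Mir375 the glandular median was 0.01. Adjusted over the list alone, the same numbers passed: 3 Hox, 3 erythroid, 2 neural, and 1 each in the striated muscle, mesenchyme, pancreas, liver, miR-34 and Dlk1-Dio3 lists. The remaining lists lay in the central range, with median log2 ratios of -0.07 for smooth muscle, -0.04 for miR-200, -0.20 for stratified and sensory epithelium, -0.28 for endothelial, -0.35 for white blood cell, -0.09 for miR-17-92, -0.04 for pluripotency, -0.18 for neural, -0.23 for mesenchyme, -0.32 for striated muscle, 0.10 for pancreas and endocrine, -0.13 for Dlk1-Dio3 and -0.39 for X-linked testis genes. With a minimum of 100 summed counts the striated muscle median turned to 0.27, over 2 genes, and the pluripotency median to 0.32, over 3. Random lists drew genes singly, while Mir144 and Mir451a share a genomic cluster, as do Mir34b and Mir34c. The same holds in let-7 for Mirlet7b and Mirlet7c-2 and for Mir98 and Mirlet7f-2, and in the glandular list for Mir192 and Mir194-2. The place of such lists among random ones may therefore overstate a joint shift.

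The scaling sets a small offset under these ratios. The median gene had a log2 ratio of -0.11 with library totals, and edgeR's TMM raised ratios by 0.13. With TMM the smooth muscle, miR-200, miR-17-92 and pluripotency medians changed sign, and Mir10b, Mir144 (-0.97), Mir449a (-0.95) and Mir451a (-0.93) came just inside the 2-fold limit. With DESeq2 size factors Mir486, at -0.98, came inside it too, the Dlk1-Dio3 median changed sign to 0.03, and Mir375 (1.01) and Mir206 came past the limit.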

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

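The test in this part was chosen after the counts were seen. Signal stood in the opposite-strand counts, which the main comparisons do not use: 19 genes had over 3 such counts in each library, and 10 of them had at least 100 summed counts and more than on the sense strand. Summed over both libraries these were 125007 counts at Gm25301, 89712 at Gm24321, 74365 at Gm25927, 37742 at Gm24083, 36878 at Gm25252, 23100 at Mir299b, 17656 at Mir142b, 9733 at Gm25750, 6320 at Mir497b and 1712 at Gm24111. They held 99.8% of opposite-strand counts in replicate 1 and 99.7% in replicate 2.

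A candidate explanation is a miRNA gene on the other strand of the listed one. In GENCODE M21, 100% of the 10 genes overlapped a miRNA gene of the other strand that the tables do not list, among them Mir378a at Gm25301 (chromosome 18, 61397813 to 61397925), Mir409 at Gm24321, Mirlet7e at Gm25927, Mir191 at Gm24083 and Mir142, a blood cell miRNA, at Mir142b. The counts may therefore belong to those genes. No biological explanation was tested.

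Reads matching several places, also outside the comparisons, numbered 2946663 in replicate 1 and 3406967 in replicate 2.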

How the results depend on the processing

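The 27 genes called between the pools became 16 with a minimum of 100 summed counts, 216 with no fold limit and 4 with edgeR's exact test; other settings gave 22 to 30. The first has fewer genes tested and the last takes the difference between the pools as error, by construction. The chi-square per degree of freedom went from 204 to 316 with a minimum of 100 and to 154 without the 10 most abundant genes. The scaling moved no called list to the other sign, and 6 or 7 lists stood outside the central range under every alternative run; the added list, pancreas and endocrine, came outside with a minimum of 100 (0.25) and with pseudocount 5 (0.10). No X-linked testis gene was left with a minimum of 100. The correlation was 0.993 with pseudocount 0.5, 0.996 with pseudocount 5, 0.995 with no minimum and 0.992 with a minimum of 100. The coefficient of variation of 0.201 became 0.219 with library totals alone, 0.196 with a minimum of 100 and 0.202 with no minimum. The root of DESeq2's median gene-wise dispersion was 0.0644, an unlike summary: a median over genes rather than 1 value fitted over all. The cause of the gap was not tested further. Detected genes rose from 369 to 601 with at least 1 count in both libraries, and without either replicate were 391. The 18 lists at or above the 95th percentile became 6 with random lists from genes with at least 10 summed counts, and 17 to 18 without either replicate. The genes holding 90% of counts numbered 57 to 62 without either replicate. The median cluster span of 4.23 became 3.96 with pseudocount 5 and 4.21 to 4.26 without either replicate. No paired analysis was possible because the labels give 1 group. Depth limits genes under about 10 counts.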

Other observations

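All tests of explanations in this part were chosen after the result was seen, except the median of the acinar pancreas genes. The list medians, the Mir122 ratio and edgeR's exact test that these tests draw on were planned. Mir122 and the erythroid genes were lower in replicate 2, though with DESeq2 size factors 0 of the 3 erythroid genes stayed past the 2-fold limit and none of these 3 passed edgeR's exact test. The erythroid median log2 ratio was -1.10 (-0.94 with DESeq2 size factors), beside Mir122 at -1.69. Both would go with more liver or blood in the replicate 1 pool, a hypothesis since it was tested on the same data. The white blood cell list stayed in the central range with a median of -0.35, and its 3 tested genes were all lower. With both strands counted, which adds Mir142b, its median over 4 genes was -0.46, at the 6.33 percentile and still in that range. The Hox-embedded list, not a liver or blood list, had a median of -1.13. More pancreas in the replicate 2 pool, where Mir375 was higher, cannot be told apart from an unchanged amount. The median of -0.43 over the acinar genes Mir216a (-1.13), Mir216b (0.36) and Mir217 (-0.43) met the bound of 0.2 set against more pancreas. But these genes went both ways near the floor. The demand that their spread and counting interval also clear the bound was added after the values were seen. Their 35 and 25 summed counts gave a log2 ratio of -0.64 whose 95% exact interval ended at 0.14. With TMM the interval ended at 0.27 and with DESeq2 size factors at 0.30, past that bound. The pancreas and endocrine list had a median of 0.10, with Mir7-2 at 0.40, Mir7b at 0.10 and Mir7-1 at 0.000378. More glandular epithelium in replicate 2 was predicted to raise both the glandular list without Mir375 and the miR-200 list. This was not seen: their medians were 0.01 and -0.039, and the latter met the bound set against more glandular epithelium. But the test cannot decide on a shift from stratified to glandular epithelium, since stratified epithelium also holds miR-200. Mir203 (-0.62) and Mir205 (-0.46) of stratified epithelium were lower, in a list with a median of -0.20. The glandular genes without Mir375 ran from -0.10 to 0.48. No other explanation for differences between the pools was tested.

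Genes with copies elsewhere stood on average below their cluster partners. In 13 of 13 clusters with both kinds of member, the mean of genes sharing a 20-base stretch with another miRNA gene was lower than the mean of members without one, by between -0.56 and -8.51 on the log2 CPM scale, with a median of -4.33. Stretches of 18 and 22 bases, also chosen after seeing the data, gave -3.81 and -4.01. A candidate explanation is that reads shared between copies were left out as multi-mapping, so that Mirlet7c-1 and Mir199a-2 may be undercounted. Single genes departed from this: Mir92-1, which shares a stretch, stood at 2542 CPM. It also leaves Mir19a at 45.7 CPM beside Mir17 at 21613 CPM unaccounted for, as Mir19a shares no such stretch. No biological explanation was tested.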
